A study of Mus musculus with 10 samples.

How the data were processed

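Liver samples of female mice, 5 Etnppl knockout and 5 wild-type, were profiled by paired-end sequencing of poly(A)-selected RNA, per the labels' protocols, with 1 library per sample. The deposited table gives FPKM for 47729 genes in 10 columns, 1 per library, rounded to 2 decimals, and the column names give the genotype and replicate number, which were matched to the titles in the labels. It also has 2 columns without a name or values, which were not used. Per the submitters' processing notes, STAR, RSEM, R 4.0.2, DESeq2 and DESeq were used and the genome build was mm10. Their roles, the annotation release, filters and strand settings are not given in the sources used here. FPKM scales each library by its own total, so a few abundant transcripts can shift the rest, and the values carry no raw counts, so no count model was fitted.

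Depth was estimated from the steps between low values. For genes with 1 annotated transcript of 350 to 1000 bases, the number of fragments and the mean fragment length of each library were fitted so that low values became whole fragments. Between 94.2% and 97.8% of the values used came within 0.1 fragment of a whole number, at 20900000 to 28300000 fragments per library. In KO replicate 3 the best fit had nearly only even numbers and was halved, to 21600000. The lengths that the authors used are not known for most genes, so counts were not rebuilt from these depths.

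Samples were grouped by genotype from the labels, and the comparison was KO against WT. Values were transformed as log2(FPKM + 0.5), and 12395 genes with a mean of at least 0.5 FPKM over the 10 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated test with trend and robust prior, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are on that scale and understate the change of genes with low values. A count at 1.5-fold or more was taken beside it. Intervals are 95% confidence intervals. The exact permutation tests were two-sided unless stated, over all regroupings of 5 against 5 libraries, with a smallest possible p of 0.00794.

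Before the data were examined, the test, the rule for named genes and the alternatives were fixed, with 26 lists of pathway genes and 12 of cell type markers that hold 713 genes in all, of which 711 were matched to the table. The lists were tested with limma camera at a preset inter-gene correlation of 0.01, and with an estimated correlation, limma fry and, added after seeing the data, the exact permutation test of each library's list mean. The neutrophil, adipose tissue and muscle lists had 4, 3 and 0 members above the filter and were not tested, leaving 35. Camera compares a list with all other genes, whose median log2 fold change was -0.05, and for 8 lists that were not called its direction differed in sign from the list's mean or median.

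The genes named were chosen by a rule. It takes Etnppl, the 10 largest changes in each direction among genes past the threshold with non-overlapping groups and a higher group mean of at least 1 FPKM, genes of lowest p to bring each direction to 5 (described by values only), passing over clone and model names, up to 4 members of lowest p in each list described, and 16 fixed genes, mostly of ethanolamine and lipid metabolism. Genes outside the rule are Hnf4a, Prepl and Mrs2, which overlap called genes, and the mitochondrial transcripts shown for comparison. Others are the highest pancreas genes, the neighbours of Etnppl and the clock genes Dbp and Nfil3 given among the observations. All of these were chosen after their values were seen. Some genes that the rule takes are not reported here.

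The alternatives were pseudocounts of 0.1 and 1, no filter or a mean of at least 0.1 or 2 FPKM, median-of-ratios scaling, rescaling to a fixed sum (TPM), quantile normalization, rescaling without the top 50 genes, no trend or robust prior, array weights, the replicate number as a block, an adjusted p of 0.1, each library left out in turn and lists without shared genes. Rescaling without mitochondrial transcripts was added after seeing the data. On simulated data with the spread of these genes and 200 changed genes in each of 5 runs, the KO against WT test over 12395 genes recovered 10.8% of 1.2-fold changes, 67.6% of 1.5-fold, 88.4% of 2-fold and 99.2% of 3-fold changes, and 5.94% of its calls were false. The simulated noise was independent between genes, and many changed genes ease the Benjamini-Hochberg threshold. These shares may therefore overstate recovery in the real comparison, where 8 genes passed.

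Coordinates are from GENCODE M21, which uses GRCm38, the assembly behind mm10, and 12362 of the 12395 tested genes had coordinates there. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.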

Results

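Livers of female mice lacking Etnppl throughout the body were compared with livers of wild-type females. Etnppl encodes ethanolamine-phosphate phospho-lyase, an enzyme that breaks down phosphoethanolamine, an intermediate of phosphatidylethanolamine synthesis. Every mouse had eaten chow for 8 weeks and then a high-fat diet with 45% of its energy from fat for 10 weeks. Poly(A)-selected RNA was sequenced from 5 knockout (KO) and 5 wild-type (WT) liver samples, 1 library each. The deposited values are FPKM, fragment numbers scaled to transcript length and to the mapped fragments of the library. The steps between low values placed the depth at 20900000 to 28300000 fragments per library, with means of 23380000 in WT and 24060000 in KO (SD 1164903 and 2961925, n = 5 each). The labels number the samples within each genotype but do not say that each came from a separate animal, so p-values measure the spread between these samples. The comparison asks which liver transcripts differ between the genotypes on this diet.

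Etnppl itself was lower in KO livers, at 8.69 ± 1.16 FPKM against 36.9 ± 11.5 FPKM in WT (mean ± SD, n = 5 each). The KO livers lay between 7.36 and 10.19 FPKM and the WT livers between 27.57 and 56.55 FPKM, so each library matched its label. The gene (ENSMUSG00000019232, plus strand of chromosome 3, 130617448 to 130637521, GRCm38) was 3.96-fold lower in KO (95% CI 3.08 to 5.10; limma adjusted p = 0.000387), and an exact two-sided permutation test gave p = 0.00794, the smallest that 5 against 5 libraries allow. KO livers kept 23.6% of the WT mean. The part of the gene that was deleted is not given in the sources used here.

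Among the other genes past the threshold, Slc3a1, which encodes the heavy subunit of a cystine and dibasic amino acid transporter, fell from 22.0 ± 3.75 to 10.6 ± 1.68 FPKM (log2 fold change -1.02, limma adjusted p = 0.00957). Hnf4aos, a non-coding antisense gene at the Hnf4a locus, rose from 1.36 ± 0.442 to 4.25 ± 0.797 FPKM (limma adjusted p = 0.00398). Hnf4a, a main transcription factor of hepatocytes, was at 160 ± 23.9 FPKM in WT and 177 ± 30.6 FPKM in KO and did not pass the test (limma adjusted p = 0.733). Gpld1, a secreted phospholipase D that cleaves glycosylphosphatidylinositol anchors, rose from 79.1 ± 3.70 to 103 ± 6.0 FPKM (limma adjusted p = 0.0449). Syne4, which encodes the nuclear envelope protein nesprin-4, rose from 1.11 ± 0.416 to 2.61 ± 0.266 FPKM (limma adjusted p = 0.0446). Unc119, a carrier of lipid-modified proteins, fell from 5.35 ± 0.428 to 3.43 ± 0.319 FPKM (limma adjusted p = 0.0446), and the mitochondrial ribosomal RNA mt-Rnr1 fell from 1646 ± 101 to 1107 ± 122 FPKM (limma adjusted p = 0.0222). In each of the 8 genes past the threshold, Etnppl included, the 5 KO values lay entirely to one side of the 5 WT values. Genes picked for so low a p are likely to show this, so it adds no support. Among all genes tested, 346 (2.79%) had such separate ranges, against 0.794% expected by chance. The gene next in line in each direction, named to complete the rule, did not pass: the paraspeckle gene Pspc1 was at 2.81 ± 0.330 FPKM in WT and 4.42 ± 0.454 FPKM in KO, and the trans-Golgi gene Tgoln1 at 70.8 ± 7.94 and 49.96 ± 4.15 FPKM (limma adjusted p = 0.0706 for both).

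**Figure D1:**
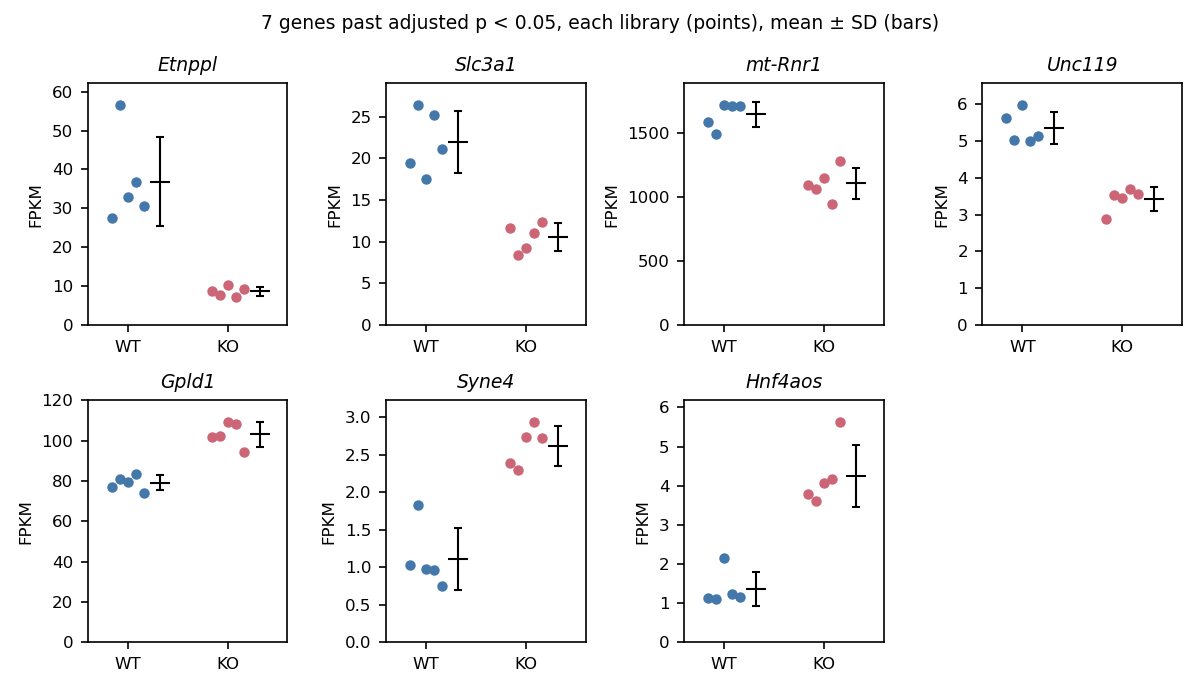
FPKM of 7 of the 8 genes past adjusted p < 0.05 in each WT (blue) and KO (red) liver, with the mean ± SD of the 5 libraries as bars beside the points and a linear axis from 0 for each gene. Etnppl, Slc3a1, mt-Rnr1 and Unc119 were lower in KO and Gpld1, Syne4 and Hnf4aos higher, without overlap.

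In all, 8 of 12395 genes tested passed an adjusted p of 0.05 in limma, 4 higher and 4 lower in KO, and 5 of them differed at least 1.5-fold, 3 higher and 2 lower. At an unadjusted p under 0.05 there were 1458 genes, 334 higher and 1124 lower, against 619.8 if genes were independent and unchanged. Other splits of the libraries gave a median of 557 and at most 1285 such genes. With median-of-ratios scaling that split was 641 higher and 644 lower. Etnppl and Hnf4aos passed under all 23 refits at other settings and Slc3a1 under 22, losing its call with the replicate number as a block (adjusted p = 0.0542), but mt-Rnr1 passed in 13, Unc119 in 10 and Gpld1 in 8 of 23, and Syne4 in 8 of 22. Across these refits the log2 fold changes ran from -0.63 to -0.52 for mt-Rnr1 and for Unc119. They ran from 0.36 to 0.43 for Gpld1 and from 0.79 to 1.215 for Syne4. With Etnppl removed before the fit, 4 genes passed. By their order of p, Unc119, Syne4 and Gpld1 were not among these, so their calls depend on the deleted gene being in the test. The count was 18 without WT replicate 2 and 4 or 5 without WT replicate 1, 3, 4 or 5 or KO replicate 1, 2 or 3. The exons of Slc3a1 and Gpld1 overlap those of Prepl and Mrs2 on the opposite strand. Whether counting used strand is not given in the sources used here, so reads from these shared exon parts cannot be told apart. Hnf4aos lies across Hnf4a on the opposite strand, with 0 bases of exon overlap. That does not exclude reads from unspliced Hnf4a RNA. Prepl and Mrs2 had log2 fold changes of 0.07 and -0.01 and did not pass.

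Among the fixed gene lists, the cholesterol synthesis genes rose together in KO livers. Of 25 members, 24 were higher in KO, with a mean log2 fold change of 0.52, and the list mean of each KO library lay above the WT mean, 4 of 5 above every WT library. No member passed over all genes tested, while 17 rose and none fell when adjusted over the list alone. Srebf2, the transcription factor that drives this pathway, went from 10.1 ± 1.1 to 13.96 ± 1.37 FPKM (n = 5 each). Mvd, a decarboxylase of the mevalonate pathway, went from 1.93 ± 0.689 to 3.96 ± 1.13 FPKM. The limma camera test with a preset correlation gave the list an adjusted p of 7.34e-22, but with an estimated correlation the adjusted p = 0.165 (0.0239 unadjusted), and an exact permutation test of the list mean gave p = 0.0238 (0.278 adjusted).

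Camera with the preset correlation called 13 of 35 lists, 11 higher and 2 lower in KO (8 and 3 with quantile normalization, where the periportal, lipoprotein and hepatocyte calls were lost). With an estimated correlation it called 0 lists (8 at an unadjusted p under 0.05, smallest adjusted p 0.138), as did the directional test of limma fry (8 unadjusted, smallest adjusted p 0.16) and the exact permutation test of list means (5 unadjusted, smallest adjusted p 0.278). The mixed test of fry, which asks for changes in either direction, called 9 lists. These were the lists of cholesterol synthesis, amino acid catabolism and urea cycle, male-biased, female-biased, periportal, hepatocyte, mitochondrial genome, ethanolamine and choline phospholipid, and antioxidant NRF2 target genes. Of all 12395 genes tested, 8070 were lower in KO, the background for the counts within lists. Random splits of the same 10 libraries gave a median of 11 called lists, so the following group results describe these livers with that limit.

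Amino acid catabolism and urea cycle genes rose in KO, 19 of 24 being higher (mean log2 fold change 0.21, camera adjusted p = 8.24e-10; adjusted p = 0.165 with an estimated correlation). Adjusted over the list alone, 5 rose and none fell, and none passed over all genes. Tat, which starts tyrosine breakdown, went from 459 ± 65.4 to 945 ± 338 FPKM, and the serine dehydratase Sds from 175 ± 44.1 to 283 ± 37.8 FPKM. The urea cycle gene Asl went from 365 ± 70.2 to 536 ± 85.7 FPKM. Periportal hepatocyte genes rose as a list (12 of 19 higher, camera adjusted p = 0.00072; adjusted p = 0.169 with an estimated correlation), with 3 rising and 1 falling when adjusted over the list alone. These included Sds, Asl and Cps1, the first enzyme of the urea cycle, at 603 ± 56.9 and 863 ± 197 FPKM, and without genes shared with other lists the periportal call was lost (adjusted p = 0.742). The glucose and insulin list rose as well (14 of 19 higher, camera adjusted p = 0.00114; adjusted p = 0.138 with an estimated correlation). Its 1 member that rose when adjusted over the list alone was Slc37a4, the glucose-6-phosphate transporter, at 75.1 ± 4.68 FPKM in WT and 94.9 ± 6.30 FPKM in KO, and the gluconeogenic Pck1 was at 1101 ± 312 and 1558 ± 319 FPKM.

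Bile acid genes rose as a list, with 17 of 19 higher and a mean log2 fold change of 0.17 (camera adjusted p = 2.83e-05; adjusted p = 0.165 with an estimated correlation), though no single member passed when adjusted over the list alone. The bile salt export pump Abcb11 was at 94.9 ± 9.35 FPKM in WT and 113 ± 8.98 FPKM in KO, and Cyp27a1 of the alternative synthesis pathway at 165 ± 26.3 and 208 ± 27.3 FPKM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, varied widely, at 18.6 ± 10.4 and 21.8 ± 6.74 FPKM, and did not pass (limma adjusted p = 0.771). Fatty acid synthesis genes also rose as a list (12 of 19 higher, camera adjusted p = 0.0052; adjusted p = 0.274 with an estimated correlation; 0.104 by camera without WT replicate 2). Fasn, the fatty acid synthase, at 26.8 ± 3.38 FPKM in WT and 41.5 ± 10.1 FPKM in KO, and the acetyl-CoA synthetase Acss2, at 17.2 ± 2.39 and 21.99 ± 0.927 FPKM, were the 2 that rose when adjusted over the list alone. Scd1, the stearoyl-CoA desaturase, was at 138 ± 66.8 FPKM in WT and 217 ± 167 FPKM in KO, a difference within the replicate spread (limma adjusted p = 0.803). Lipoprotein genes (12 of 21 higher, camera adjusted p = 0.00664) and xenobiotic metabolism genes (17 of 23 higher, camera adjusted p = 0.00116) rose by small amounts, with mean log2 fold changes of 0.04 and 0.16, and had adjusted p = 0.177 and adjusted p = 0.418 with an estimated correlation. No member of either list passed when adjusted over the list alone, and the xenobiotic call ended without WT replicate 2 (adjusted p = 0.127) or KO replicate 1 (adjusted p = 0.130).

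**Figure D2:**
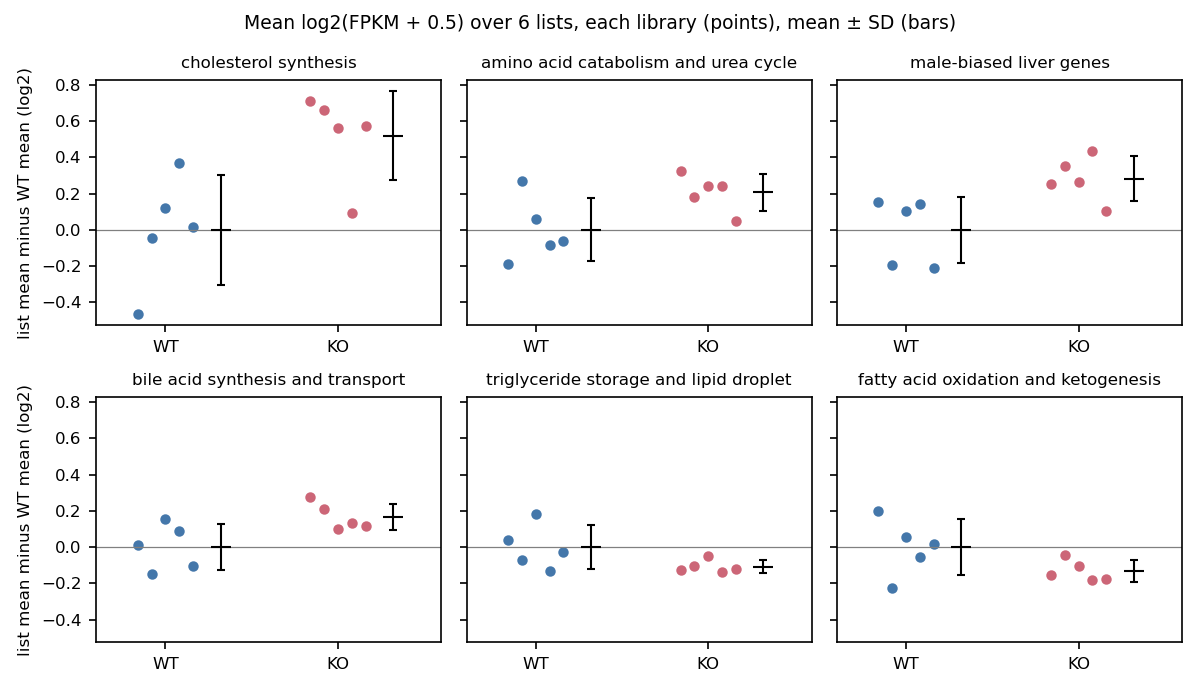
Mean log2(FPKM + 0.5) over the tested members of 6 gene lists in each WT (blue) and KO (red) library, as the difference from the WT mean, with mean ± SD as bars. The cholesterol synthesis means are spread most, from -0.46 in a WT library to 0.71 in a KO library, and the WT and KO ranges overlap in each of the 6 lists.

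Fatty acid oxidation and ketogenesis genes fell as a list, 28 of 32 being lower in KO (mean log2 fold change -0.13, camera adjusted p = 0.023; adjusted p = 0.769 with an estimated correlation), and no member passed when adjusted over the list alone. The call was lost without WT replicate 1, 3 or 5 or KO replicate 4 or 5 (highest adjusted p = 0.222, without WT replicate 1). The mean log2 fold change was then -0.08 without WT replicate 1 and -0.13 to -0.12 in the others of these refits. Cpt1a, which controls fatty acid entry into mitochondria, was at 257 ± 23.5 FPKM in WT and 217 ± 27.4 FPKM in KO, and the thioesterase Acot2 at 36.1 ± 8.28 and 23.96 ± 3.71 FPKM. The hormone gene Fgf21 was at 38.7 ± 15.1 and 25.5 ± 4.55 FPKM. In the triglyceride storage and lipid droplet list, 17 of 26 genes were lower, about the share among all genes tested, and the list did not pass (camera adjusted p = 0.498). Pparg, the transcription factor that promotes lipid storage, at 8.47 ± 1.41 FPKM in WT and 5.63 ± 1.13 FPKM in KO, was the 1 member that fell when adjusted over the list alone. The lipid droplet coat gene Plin2 was at 566 ± 147 and 416 ± 45.9 FPKM, Cidec at 10.5 ± 3.27 and 7.17 ± 3.71 FPKM and the fatty acid transporter Cd36 at 134 ± 29.4 and 115 ± 15.6 FPKM, none past the test.

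In ethanolamine and choline phospholipid metabolism, the pathway to which Etnppl belongs, 8 of 25 genes were higher and 17 lower. The list did not pass by camera (adjusted p = 0.945). The mixed test of fry called it for changes in either direction (adjusted p = 0.0016). Etnk1, an ethanolamine kinase that makes phosphoethanolamine, fell from 12.1 ± 1.06 to 9.03 ± 0.860 FPKM when adjusted over the list alone, without overlap between the groups, and the betaine-homocysteine methyltransferase Bhmt rose from 3472 ± 934 to 5026 ± 547 FPKM by the same measure. Neither passed over all genes (limma adjusted p = 0.118 and 0.194). The other ethanolamine kinase, Etnk2, was at 152 ± 25.7 FPKM in WT and 198 ± 40.6 FPKM in KO. Pcyt2, which converts phosphoethanolamine to CDP-ethanolamine, was at 295 ± 14 and 296 ± 20.5 FPKM, a log2 fold change of 0.00 with a 95% CI of -0.13 to 0.14, and Pemt, which methylates phosphatidylethanolamine, at 229 ± 14.9 and 225 ± 21.1 FPKM. Phykpl, the close relative of Etnppl that acts on phosphohydroxylysine, was at 10.4 ± 0.965 and 11.1 ± 1.51 FPKM, and Sgpl1, which releases phosphoethanolamine from sphingosine phosphate, at 18.7 ± 1.82 and 17.4 ± 0.530 FPKM.

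Sex-biased liver genes moved in both directions. Of 22 female-biased genes, 9 were higher and 13 lower, and the list did not pass (camera adjusted p = 0.527). Its members still changed in either direction by the mixed test of fry (adjusted p = 3.51e-06). Cyp2a4, a steroid hydroxylase, at 132 ± 32.8 FPKM in WT and 60.1 ± 20.6 FPKM in KO, and the peroxisomal transporter Abcd2, at 19.2 ± 2.38 and 13.9 ± 1.25 FPKM, fell when adjusted over the list alone. The male-biased list rose (10 of 15 higher, mean log2 fold change 0.28, camera adjusted p = 0.000659; adjusted p = 0.144 with an estimated correlation), with 4 rising and 1 falling when adjusted over the list alone. Susd4 went from 0.782 ± 0.294 to 2.09 ± 0.533 FPKM and the cytochrome P450 gene Cyp2u1, which lies near Etnppl, from 1.98 ± 0.646 to 3.52 ± 1.11 FPKM, whereas the major urinary protein gene Mup20 fell from 39.2 ± 10.5 to 22.4 ± 3.25 FPKM. Cyp2a4 and Mup20 belong to families of near-identical copies, so how reads were split among the copies is uncertain.

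Transcripts of the mitochondrial genome were lower in KO unevenly. Their list of 9 protein-coding genes tested fell (8 lower, mean log2 fold change -0.17, camera adjusted p = 0.0332; adjusted p = 0.707 with an estimated correlation), and mt-Nd2 and mt-Nd6 fell when adjusted over the list alone. The list call was lost without WT replicate 2, 3 or KO replicate 2, 5 (highest adjusted p = 0.263, without KO replicate 2), with array weights, with no filter and with the replicate block (adjusted p = 0.0542). The mean log2 fold change was then -0.11 without KO replicate 2 and -0.18 to -0.13 in the others of these refits. KO livers had 67.3% of the WT mean for mt-Rnr1, 72.3% for mt-Rnr2, 74.5% for mt-Nd6 and 76.6% for mt-Nd2, each without overlap, but 100.4% for mt-Co1, 98.2% for mt-Nd4l and 94.4% for mt-Cytb. The mitochondrial genome took 12.6 ± 1.03% of the FPKM in WT and 11.6 ± 1.02% in KO (mean ± SD, n = 5 each; exact two-sided permutation p = 0.151). The genes mt-Atp6, mt-Atp8 and mt-Co2 are listed at 0 in every library and mt-Co3 is below 1 FPKM in every library, so the mitochondrial share leaves these 4 out. Nuclear genes of the respiratory chain did not pass as a list (20 of 33 higher, camera adjusted p = 0.0641).

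**Figure D3:**
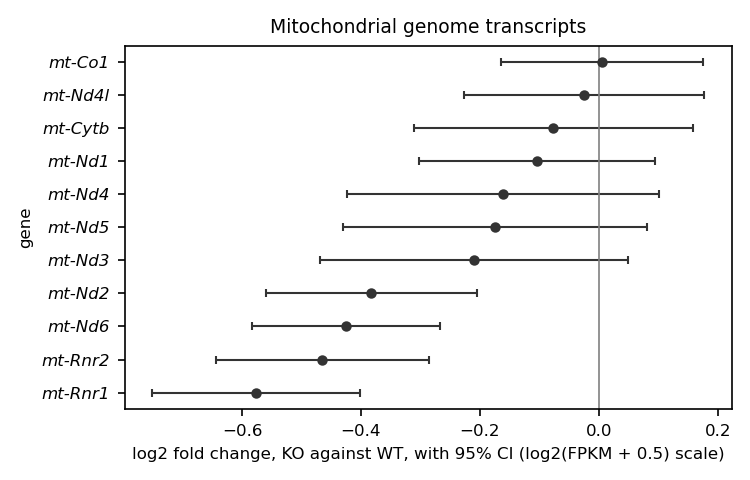
Log2 fold change of KO against WT with its 95% confidence interval from limma for the 11 mitochondrial genome transcripts tested, on the log2(FPKM + 0.5) scale. The intervals of mt-Rnr1, mt-Rnr2, mt-Nd6 and mt-Nd2 lie below 0 and that of mt-Co1 is centred near 0.

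Markers of liver cell types showed little difference between the genotypes. Hepatocyte markers rose slightly (11 of 13 higher, mean log2 fold change 0.09, camera adjusted p = 0.00225; adjusted p = 0.161 with an estimated correlation), and Ahsg, a secreted plasma protein gene, was at 6796 ± 695 FPKM in WT and 8274 ± 1068 FPKM in KO. Markers of Kupffer cells and macrophages (4 of 16 higher), sinusoidal endothelium (6 of 14 higher), stellate cells and fibroblasts (1 of 18 higher), lymphocytes (5 of 14 higher), cholangiocytes (5 of 10 higher) and erythroid cells (1 of 5 higher) did not pass (lowest camera adjusted p = 0.498). Among monocyte, dendritic cell and lipid-associated macrophage markers 10 of 11 were lower (camera adjusted p = 0.114), and Cd9 fell from 8.03 ± 1.43 to 5.44 ± 0.756 FPKM when adjusted over the list alone. The exocrine pancreas markers were called higher by camera (adjusted p = 0.000659; adjusted p = 0.675 with an estimated correlation), and 1 library carried the difference: their FPKM summed to 231 in KO replicate 3 and to between 2.35 and 5.68 in the other 9 libraries. Without KO replicate 3, fewer than 5 of these markers reached the filter, and 16 lists were called, among them 12 of the 13 called in all libraries.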

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

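The tests in this part were chosen after the results were seen. Groups of 5 libraries were examined for 63 of the genes named in the text, 35 lists and library measures, in WT and KO. Of these 216 groups, 19 had 1 library set apart from the other 4 by more than 0.71 of the group's range. By chance about 1 in 20 groups would, or 10.8 here.

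Exocrine pancreas transcripts in KO replicate 3 are consistent with a trace of pancreatic tissue in 1 library: all 14 list genes had their highest value in that library, led by Ctrb1 at 56.41, Cela2a at 49.7 and Clps at 30.44 FPKM, with Cela1 at 16.35 FPKM, and the set made up 0.0319% of its FPKM. An induction by the genotype is argued against, as the summed FPKM of 0 of the other 4 KO libraries exceeded the highest WT library (3.38 against 5.68). Of the 14 genes, Cela1 was also at 2.08 to 3.14 FPKM in the other 9 libraries. The list score of this library lay 4.5799 (log2) above the WT mean and its sum was 231.09 FPKM. At a far lower level, WT replicate 5 stood apart from the other WT libraries, with Cela2a at 0.89 FPKM, Clps at 1.13 FPKM, a list score 0.3695 above the WT mean and a sum of 5.68 FPKM.

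WT replicate 2 stood apart in its median Spearman correlation with the other libraries (0.9787, the next WT library at 0.9822), in Syne4 (1.83 FPKM, next 1.03) and in the score of monocyte, dendritic cell and lipid-associated macrophage markers (0.4932 above the WT mean, log2). KO replicate 5 stood apart in Gclc (97.15 FPKM, next 81.88), Hnf4aos (5.62 FPKM, next 4.16) and Pparg (7.59 FPKM, next 5.44). Hnf4aos was at 2.15 FPKM in WT replicate 3, with the next WT library at 1.24 FPKM. The cholesterol synthesis score of KO replicate 4 was 0.0946 above the WT mean, where the next KO library was at 0.5599, and the sinusoidal endothelium score of KO replicate 1 was -0.2059, where the next was at 0.0203. The first principal component (18.8% of the variance) separated the genotypes only in part (exact two-sided permutation p = 0.0238, adjusted p = 0.167 over 7 library measures).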

How the results depend on the processing

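Rescaling without mitochondrial transcripts and the exact permutation test of list means were chosen after seeing the data. Etnppl stayed lower and past the threshold in all 23 refits, with log2 fold changes of -2.08 to -1.82. The count of 8 changed genes became 5 with no filter (4 of the 8 shared), 5 without trend and robust prior (all shared), 18 with array weights (all 8 included), 5 with the replicate block (3 shared) and 30 at an adjusted p of 0.1, and it ran from 4 (without WT replicate 1 or 5, or KO replicate 2) to 18 (without WT replicate 2) as libraries were left out. The count of 5 genes changed at least 1.5-fold became 9 with array weights and ran from 4 to 12 (without WT replicate 2). The count of 13 lists became 0 with an estimated correlation, with directional fry and with the exact permutation test (mixed fry, which has no direction, called 9), and ran from 10 (without WT replicate 2) to 16 (without WT replicate 4 or KO replicate 3) as libraries were left out. The cause of these changes was not tested, apart from the looser threshold. WT replicate 2 had the largest residual SD, 0.258, against 0.21 to 0.242 in the other libraries.

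No called gene or list changed direction while called. Of 3517 values of named genes, 26 had the opposite sign and of 941 values of lists, 55, each in a result not called in either fit. Of the named gene values 3452 kept their side of the threshold, 53 lost and 12 gained a call, and of the list values 855, 58 and 28. Whether replicate numbers pair the samples was not settled. Correlations of the residuals of same-numbered WT and KO libraries ran from -0.02 to 0.20, with 2 of 5 above 0.1. Among the 5 libraries of the other genotype, 5 of 10 libraries correlated best with their own number. No chance level was computed for these values. Among clock genes, picked after their values were seen, Nfil3 fell steadily from replicate 1 to 5 in WT (21.65 to 6.48 FPKM) and KO (28.87 to 9.15 FPKM). Dbp was higher in replicate 5 than in replicate 1 in WT (46.24 against 2.71 FPKM) and KO (17.33 against 1.13 FPKM). Ciart rose between these replicates in WT and fell in KO. Replicate numbers thus shared an order in some clock genes but not all, and a pairing of the samples is neither shown nor excluded. A depth near 20900000 to 28300000 fragments limits genes near the filter, where values rest on few fragments. Changes of 1.2-fold were recovered in 10.8% of simulated cases, so a small change that was not called is not shown to be absent.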

Other observations

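Of the tests in this part, the one on RNAs without a poly(A) tail had its prediction written before its result was seen, and the tests on splits (with and without Etnppl), scaling, feeding state, the mitochondrial gap and the window around Etnppl were chosen after. No list of stress or defence genes passed by camera, and their counts of lower members stand against 8070 of 12395 genes lower among all tested. Of 19 antioxidant targets of NRF2, 13 were lower (camera adjusted p = 0.114; adjusted p = 0.000952 by the mixed test of fry, which called the list for changes in either direction), and Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, at 110 ± 14.3 FPKM in WT and 83.7 ± 7.58 FPKM in KO (mean ± SD, n = 5 each), and the quinone reductase Nqo1, at 7.64 ± 0.977 and 5.89 ± 0.592 FPKM, fell when adjusted over the list alone. In the acute phase list 14 of 22 were lower (camera adjusted p = 0.740), and the metalloreductase Steap4, at 53.6 ± 6.20 and 37.6 ± 5.93 FPKM, fell when adjusted over the list alone. Of unfolded protein and integrated stress response genes 14 of 21 were lower (camera adjusted p = 0.807), and the stress hormone gene Gdf15 was at 14 ± 3.67 and 8.58 ± 2.43 FPKM without passing. Interferon response genes (19 of 22 lower, camera adjusted p = 0.598) and immediate early and heat shock genes (14 of 18 lower, camera adjusted p = 0.642) did not pass. Circadian clock genes (9 of 19 higher, camera adjusted p = 0.598), cell cycle genes (6 of 8 higher, camera adjusted p = 0.590), alcohol and aldehyde metabolism genes (11 of 17 higher, camera adjusted p = 0.114) and pericentral hepatocyte genes (9 of 21 higher, camera adjusted p = 0.060) did not pass either. Clock genes run in opposite phases, so a test of shared direction can miss a shift in their timing. The mixed test of fry did not call the clock list (adjusted p = 0.496), but some clock genes spread widely within a genotype, which weakens it. Dbp ran from 2.71 to 46.24 FPKM in WT and from 1.13 to 17.33 FPKM in KO. Nr1d1 was at 63.9 ± 13.6 FPKM in WT and 46.7 ± 13.3 FPKM in KO, and Nr1d2 at 16.3 ± 4.10 and 11.4 ± 2.55 FPKM. Cry1 was at 3.27 ± 0.330 and 4.51 ± 1.32 FPKM. None of the 19 passed when adjusted over the list alone. A difference in clock timing is thus neither shown nor excluded.

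The fixed list of genes near Etnppl did not pass (9 of 25 higher, camera adjusted p = 0.446). In a window of 10 Mb to each side of Etnppl, chosen after seeing the data, 16 of 75 tested genes had an unadjusted p under 0.05 (21.3%), against 1435 of 12286 elsewhere (11.7%; Fisher's exact test two-sided p = 0.0173, across genes, which are not independent replicates). None of the 75 passed over all genes. The lowest p was that of Gimd1, at 2.97 ± 0.403 FPKM in WT and 1.73 ± 0.393 FPKM in KO. The list of genes that differ between C57BL substrains did not pass (2 of 7 higher, camera adjusted p = 0.217), and Nnt, a gene deleted in part in one of these substrains, was at 54.3 ± 2.42 and 48.3 ± 2.25 FPKM, present in both groups.

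The gene counts and list count were set against 100 of the possible splits of the 10 libraries into 5 and 5, the real one included. As many as 8 genes were called in 1 split, the real one, with 5 in the highest other split. As many as 5 genes at 1.5-fold were called in 1 split, with 4 in the highest other. Both counts include Etnppl, the deleted gene, which differs by design, so they cannot exclude chance for the other genes. With Etnppl removed before each fit, the real split gave 4 genes, 3 of them at 1.5-fold, and the highest other split 5 and 4. By their order of p, Unc119, Syne4 and Gpld1 were the genes lost. Counts as large arose in 2 of the 100 splits for each count, a share under 0.05, although another split gave more than the real one. The count of 8 was also 4 without WT replicate 1 or 5 or KO replicate 2, 5 without WT replicate 3 or 4 or KO replicate 1 or 3, and 18 without WT replicate 2, where the count at 1.5-fold was 12. As many as 13 lists were called in 32 of the 100 splits, with 21 in the highest other, so chance cannot be excluded for the list count.

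Cholesterol synthesis genes, higher in KO, had the lowest p of the 35 lists by camera with the preset correlation, but not with an estimated correlation or by fry. A camera p as small for this list arose in 4 of the 100 splits, the smallest other p being 1.17e-28 against 2.1e-23, a share under 0.05, but the list was singled out of 35 after seeing the data. A scaling effect is argued against, since the mean log2 fold change stayed between 0.51 and 0.57 in the 5 scaling alternatives. KO livers taken in a more fed state could raise this pathway, and 16 fasting response genes then should be lower; their mean difference was 0.16 (exact permutation p = 0.270), with 9 higher and 7 lower, so feeding state stays open. An effect of the genotype, the design's own explanation, is a hypothesis that these data do not separate from feeding state. A difference in clock timing is not excluded either, and whether it bears on this list was not tested.

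The lower mt-Rnr1, mt-Rnr2, mt-Nd2 and mt-Nd6 values in KO could arise from less mitochondrial RNA overall. That would lower all mitochondrial transcripts alike, but the gap between these 4 and the other 7 differed by -0.36 (log2) between KO and WT, and a gap as wide arose in few regroupings when the 4 lowest were chosen again in each, a step added after a first version without it was seen (one-sided exact permutation p = 0.0119). A poorer recovery of RNAs without a poly(A) tail could lower the ribosomal RNAs. A set of 14 other RNAs that mostly lack a tail, chiefly histone transcripts, differed by -0.15 (exact permutation p = 0.254, and -0.21 to -0.07 with each library left out). In poly(A)-selected libraries the reads of these RNAs may come from forms with a tail, so the set cannot decide this. Poorer recovery would not account for mt-Nd2, which is polyadenylated, and whether it could account for mt-Nd6 was not tested. A difference in mitochondrial DNA type between the mouse lines was not tested, and a genotype effect stays open.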
